A study of Mus musculus with 12 samples.

How the data were processed

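RNA sequencing libraries came from 4 groups of 3, which are control (MCM/+) and Wls fl/fl (MCM/+ with floxed Wls) hearts, each as a cardiomyocyte (CM) and a non-cardiomyocyte (NonCM) fraction, grouped by the genotype and fraction in the labels. Libraries were matched to replicates by the library numbers in the sample titles and table columns, and all 12 were used.

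The submitters' processing notes list STAR, DESeq2 and the mouse build mm10, without versions. The annotation, the counting tool, its use of strand and any trimming are not given in the sources used here. The deposited tables, 1 per fraction, hold for each library a signal value, the normalized read count, which the authors made by dividing each library's gene counts by a size factor within that table. This was checked on the values, since 100% of the values of every library were whole multiples of a step, to a tolerance of 0.01 reads, and the mean over the 6 libraries equalled the deposited mean column to a relative difference of at most 4.5e-09. Per the file headers, the tables also give the authors' log2 fold changes with standard errors, and the authors' p-values and adjusted p-values from DESeq2. A DESeq2 fit on the recovered reads gave log2 fold changes within 4.2e-08 (CM) and 4.8e-08 (NonCM) of the deposited ones. With counts unavailable as such, limma on normalized values was used as the choice made for such values.

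Each table holds 46983 gene symbols, of which 20454 (CM) and 17974 (NonCM) had no read, and 27 in each had been turned into dates and could not be named. Of all symbols, 44027 (93.7%) matched exactly 1 gene of GENCODE M21, from which positions on GRCm38 (mm10) were taken.

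The main test, run within each fraction because the tables were scaled apart, was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(value + 1) of genes with a mean value of 10 or more, Wls fl/fl minus control with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 49 in number, were tested by limma's camera with a preset correlation of 0.01 where at least 5 members were tested, again with an estimated correlation, and by fry, each adjusted over lists. Camera compares a list with all other genes, while fry asks whether its members move, on balance, one way. Members were also adjusted over the list alone. Groups of 3 cannot reach an exact permutation p under 0.1, so single genes have no separate exact test.

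Genes were named by rule: Wls; the 10 largest rises and 10 largest falls per fraction among called genes with non-overlapping groups and a mean of 50 or more, leaving out symbols that end in Rik or begin with LOC or with Gm, BC, AC or AL and digits; the 4 members of smallest p of each called list; up to 2 called members of other lists; and each Wnt ligand with a mean of 10 or more. Chance gives non-overlapping groups to 10% of genes with 3 against 3. The lists, the tests, the naming rule and most alternatives were chosen before the data were examined. The alternatives without replicate 3 of both genotypes, limma-voom, and the joint fit of both fractions, with and without a block, were added after the data were seen.

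Alternatives were TMM and upper-quartile scaling, no filter, a mean of 50, pseudocounts of 0.5 and 5, DESeq2 1.42.0, edgeR 4.0.16 (quasi-likelihood) and limma-voom on recovered reads, each library left out in turn, a score of the other fraction's markers or of sex-linked genes as covariate, an adjusted p of 0.1, and an absolute log2 change of at least 1. Effects of genotype were compared between fractions by the interaction of fraction and genotype in a joint edgeR fit of recovered reads from 12 libraries, with fry for lists. The authors' DESeq2 columns were used only beside the main test.

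The code was tested on simulated counts with 200 changed genes per fraction. In CM (11930 genes) limma recovered 70 of 100 genes changed by 0.5 and 99 of 100 changed by 1 on the log2 scale, with 9 false calls among 178, and edgeR recovered 72 and 99. In NonCM (13192 genes) limma recovered 52 and 97 of 100, with 0 false calls among 149 (edgeR 87 and 100, with 9 false among 196). A simulated raised list had a camera adjusted p of 0.00697 (CM) and 0.00865 (NonCM) with an estimated correlation. Its genes were drawn independently, and replicate 3 as a separate library. In the data the estimated correlation was 0.397 for oxidative phosphorylation in CM and 0.579 for mature cardiomyocyte markers in NonCM. The simulation therefore does not show that this test would find a raised list of correlated genes. Depth ranged from 1160146 to 10281214 recovered reads per library, so that in the shallowest library 1 read equals a normalized value of 5.54.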

Results

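RNA was sequenced from mouse hearts, injured as neonates, that had been separated into a cardiomyocyte fraction (CM) and a fraction of the remaining cells (NonCM). Control mice carried the MCM/+ genotype, and the other mice carried MCM/+ with floxed Wls (Wls fl/fl). MCM is the usual short name of MerCreMer, a Cre recombinase placed between estrogen receptor domains so that it works after tamoxifen. Wls (Wntless) carries Wnt proteins through the secretory pathway to the cell surface. Mice received 3 doses of tamoxifen between postnatal days 1 and 3, had a myocardial infarction at postnatal day 2, and gave tissue 2 weeks after surgery, although sample labels call the cells adult. The series description states 3 hearts per condition, and each of the 4 groups of genotype and fraction holds 3 libraries. The comparison asks what the heart's muscle cells and its other cells express when Wls is targeted in cardiomyocytes that carry the MCM allele. Its loss is meant to keep those cells from releasing Wnt ligands, and release itself was not measured here. The series is about noncanonical Wnt signals sent from cardiomyocytes to fibroblasts during neonatal regeneration.

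The deposited values are normalized read counts per gene. Recovered reads numbered 6192140, 5171769 and 6517002 in CM control replicates 1 to 3 and 5439266, 6107711 and 9775856 in CM Wls fl/fl replicates 1 to 3. In NonCM they numbered 1160146, 8963762 and 9262307 in control replicates 1 to 3 and 10281214, 9725690 and 8608352 in Wls fl/fl replicates 1 to 3, so that NonCM control replicate 1 was the shallowest library. The 2 fractions were normalized apart. Changes below are log2 differences of Wls fl/fl minus control within a fraction, by limma on log2(value + 1). For genes with few reads this scale can understate the change. It can also overstate it, since 1 read in NonCM control replicate 1 equals a normalized value of 5.54. Wnt4 in NonCM had no read in that library and a larger change by limma than by edgeR. Means are given ± SD over n = 3 libraries. P-values and adjusted p-values measure the spread between these libraries. In each of the 4 groups, the profile of replicate 3 lay near a weighted mean of replicates 1 and 2. Mean squared residuals were at most 1.04 times the counting variance of replicate 3 and that weighted mean together (the 1% largest left out). Results without replicate 3 of both genotypes are therefore given beside the counts of changed genes.

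Both fractions held much cardiomyocyte RNA. The 28 mature cardiomyocyte markers took 12.4 ± 0.1% of all normalized reads in CM control and 12.5 ± 0.551% in CM Wls fl/fl libraries, and 8.43 ± 0.397% and 7.07 ± 0.175% in the NonCM groups. Fibroblast markers took 0.169 ± 0.00451% and 0.17 ± 0.0186% in CM, against 1.47 ± 0.0458% in NonCM control and 2.08 ± 0.0624% in NonCM Wls fl/fl libraries. Macrophage markers took 0.00992 ± 7.7e-04% and 0.01 ± 2.5e-04% in CM and 0.218 ± 0.021% and 0.281 ± 0.0128% in NonCM. Endothelial markers differed less between fractions, at 0.319 ± 0.02% and 0.304 ± 0.0101% in CM and 0.485 ± 0.016% and 0.443 ± 0.00794% in NonCM.

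Wls, the floxed gene (mouse build mm10, chromosome 3, 159839672 to 159938664), fell in CM and differed less in NonCM, a fraction that also holds cardiomyocyte RNA. In CM its normalized read count was 243, 201 and 210 in control replicates 1 to 3 and 91.6, 57.3 and 93.9 in Wls fl/fl replicates 1 to 3. The means were 218 ± 22.1 and 80.9 ± 20.5 (log2 change −1.45, SE 0.17, limma adjusted p = 0.00389), lower in 3 of 3 Wls fl/fl libraries. Without CM control replicate 3 the change was −1.47 with adjusted p = 0.052, and without replicate 3 of both genotypes it was −1.60 with adjusted p = 0.0898. In NonCM the counts were 427, 374 and 407 in control and 356, 323 and 316 in Wls fl/fl replicates 1 to 3, a change of −0.28 (SE 0.08, limma adjusted p = 0.0831). It passed by edgeR (−0.25, adjusted p = 0.0327), limma-voom (−0.25, adjusted p = 0.0368) and limma without NonCM control replicate 1 (−0.24, adjusted p = 0.0489). By DESeq2 it did not pass (adjusted p = 0.218), nor by limma with any other library left out. Limma adjusted p was 0.202 without control replicate 3, 0.294 and 0.334 without Wls fl/fl replicates 2 and 3, and 0.578 without replicate 3 of both genotypes. The effect of genotype on Wls differed between the fractions (NonCM minus CM 1.17, edgeR interaction adjusted p = 0.0112). These are counts over the whole gene, and the sources used here do not say which exons are floxed, so reads that remain cannot be placed inside or outside the deleted part.

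**Figure D1:**
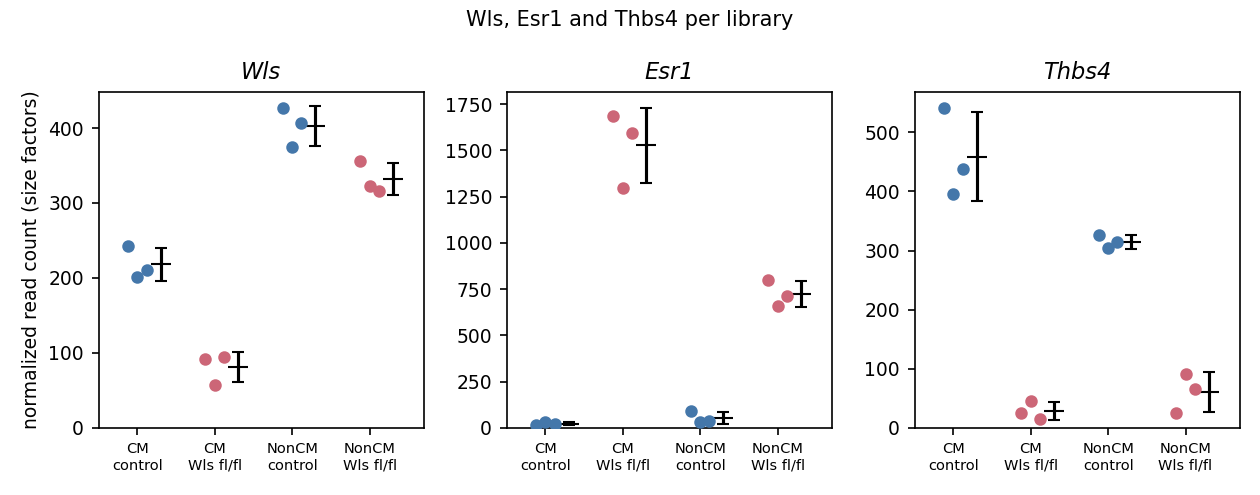
Normalized read counts per library of Wls, Esr1 and Thbs4 in control (blue) and Wls fl/fl (red) hearts of both fractions, with points for libraries and lines and bars for the mean ± SD of 3 libraries. In CM, Wls lay between 57.3 and 93.9 in the Wls fl/fl libraries and between 201 and 243 in the controls.

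In cardiomyocytes few single genes differed between genotypes. Besides the loss of Wls, the estrogen receptor gene Esr1 was far higher, the matrix glycoprotein gene Thbs4 was almost lost, and the transferrin receptor gene Tfrc rose. By camera with a preset correlation, lists of mitochondrial respiration, fatty acid oxidation, glycolysis, basement membrane and interferon-stimulated genes were called up and endothelial markers down, each by a small amount. None of the 43 tested lists was called with an estimated correlation (lowest adjusted p = 0.324).

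Of 11944 genes tested in CM by limma, 8 rose and 3 fell at an adjusted p under 0.05, and all 11 were also called by edgeR and in the deposited DESeq2 table. An unadjusted p under 0.05 was reached by 1044 genes, where 597 would be reached by chance. By edgeR it was reached by 1055, where 600 would be. The excess was absent by limma without replicate 3 of both genotypes (476, where 597 would be). By DESeq2 it was reached by 407 of all genes with a p-value, while chance would give 426 among only the 8526 with an adjusted p. These 2 numbers cover different genes, and the 407 shows no excess. Esr1 (chromosome 10, 4611593 to 5005614) rose from 22.4 ± 9.83 to 1527 ± 203 (log2 change 6.10, SE 0.22, adjusted p = 4.3e-08). The labels give MCM/+ to both genotypes, and no group holds floxed Wls without MCM or separates a difference in that allele from the loss of Wls. Thbs4 (thrombospondin 4; chromosome 13, 92751590 to 92794818) fell from 459 ± 74.9 to 29.1 ± 15.4 (log2 change −4.05, SE 0.28, adjusted p = 3.6e-05). Tfrc, the transferrin receptor that brings iron into cells, rose from 3198 ± 344 to 4941 ± 36.3 (0.63, adjusted p = 0.00153), and Alas1, the rate-limiting enzyme of heme synthesis, rose by 0.35 (adjusted p = 0.0159). Ndrg4, a cytoplasmic protein needed for cardiomyocyte growth in fish embryos, rose from 675 ± 29.1 to 1151 ± 136 (0.76, adjusted p = 0.00153). Prkg1, a cGMP-dependent kinase (chromosome 19, 30564489 to 31765033), rose from 138 ± 22.1 to 248 ± 14.3 (0.85, adjusted p = 0.00893). Nnt, a mitochondrial enzyme that makes NADPH, rose by 0.33 (adjusted p = 0.0086), Fam81a by 0.75 (adjusted p = 0.0159) and the membrane glycoprotein gene Mdga1 by 0.69 (adjusted p = 0.0262). Ces1d, a carboxylesterase that splits lipid esters, fell by 1.12 (SE 0.14, adjusted p = 0.00872).

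Esr1, Thbs4, Tfrc and Ndrg4 kept their limma calls in CM whichever single library was left out. Alas1, Ces1d, Nnt and Prkg1 lost theirs without CM control replicate 3 (adjusted p = 0.14, 0.105, 0.105 and 0.105) and without CM Wls fl/fl replicate 3 (adjusted p = 0.133, 0.0596, 0.0626 and 0.0887). Fam81a lost its call without CM control replicate 3 (adjusted p = 0.129) or Wls fl/fl replicate 1, 2 or 3 (adjusted p = 0.0861, 0.0661 and 0.0596). Mdga1 lost its call without CM control replicate 2 or 3 (adjusted p = 0.0544 and 0.245) or Wls fl/fl replicate 1, 2 or 3 (adjusted p = 0.0792, 0.117 and 0.196). The count of 11 genes became 18 without control replicate 1, 17 without control replicate 2, 5 without control replicate 3, 17 without Wls fl/fl replicate 2 and 5 without Wls fl/fl replicate 3. Without replicate 3 of both genotypes, limma and edgeR each called 2 genes, Esr1 and Thbs4. All 11 kept their direction by edgeR, which is no independent check, since the remaining libraries were among those that gave the calls.

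Of 43 gene lists with at least 5 tested members in CM, camera called 8, of which 6 were up and 2 down. With an estimated correlation camera called 0, the lowest adjusted p being 0.324, and fry called 1. Without replicate 3 of both genotypes camera called 6 and fry 0 (lowest fry adjusted p = 0.686). All 48 tested genes of nuclear-encoded oxidative phosphorylation were higher in Wls fl/fl libraries, with a median change of 0.10 (camera adjusted p = 4.6e-16; adjusted p = 0.539 with an estimated correlation). No member passed by limma, edgeR or DESeq2, over all genes or adjusted over the list alone, and 18 had an unadjusted limma p under 0.05. Uqcrfs1, the iron-sulfur subunit of complex III, read 3728 ± 90.1 and 4201 ± 163 (0.17), and Cox5b of complex IV read 2644 ± 98.1 and 2944 ± 51.3 (0.16). Fatty acid oxidation had a median change of 0.07 (camera adjusted p = 2.0e-04; fry adjusted p = 0.0423; adjusted p = 0.324 with an estimated correlation). None of its 28 tested members passed by limma, edgeR or DESeq2 over all genes, 7 had an unadjusted limma p under 0.05, and 4 were up adjusted over the list alone. Among them, the log2 difference was 0.19 for Eci1, an isomerase for unsaturated fatty acids, and 0.18 for Cpt2, which makes acyl-CoA inside mitochondria. Glycolysis had a median change of 0.08 (camera adjusted p = 2.2e-04; adjusted p = 0.539 with an estimated correlation), with 0 of 21 members past the threshold by limma or edgeR, 0 of the 18 with an adjusted p by DESeq2, 8 at an unadjusted limma p under 0.05 and 3 up adjusted over the list alone. Its lowest p belonged to Pfkl, the liver form of phosphofructokinase, with a change of 0.27.

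Basement membrane and other matrix genes had a median change of 0.12 in CM (camera adjusted p = 2.1e-04; adjusted p = 0.539 with an estimated correlation). By limma and edgeR, 0 of 28 members passed, DESeq2 called 1 of the 27 with an adjusted p, 10 had an unadjusted limma p under 0.05, and 3 were up adjusted over the list alone. The log2 differences of the collagen IV genes Col4a1 and Col4a2, which lie side by side, were 0.24 and 0.18. Myofibroblast and fibrosis genes had a median change of 0.11 and a mean of −0.03, the signs differing because of Thbs4, and camera called the list up (adjusted p = 0.0485; adjusted p = 0.539 with an estimated correlation). Of its 26 tested members only Thbs4 passed by limma, and 2 were up and 1 down adjusted over the list alone. Fibronectin, Fn1, read 570 ± 34.2 and 730 ± 28.8 (0.36, limma adjusted p = 0.0682), and Postn, a fibroblast activation marker, differed by 0.34 (adjusted p = 0.338). This list lost its call without CM control replicate 2 (adjusted p = 0.122), control replicate 3 (0.136), Wls fl/fl replicate 2 (0.489) or Wls fl/fl replicate 3 (0.0793). Late scar fibroblast genes were called down with a median of −0.12 (camera adjusted p = 0.0422; adjusted p = 0.539 with an estimated correlation). Thbs4 was the only one of the 6 tested to pass by limma, and 2 were down adjusted over the list alone, Thbs4 and Clu, a secreted chaperone (−0.22). The call ended without CM control replicate 1 (adjusted p = 0.0738), control replicate 3 (0.207) or Wls fl/fl replicate 1 (0.148).

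Interferon-stimulated genes had the largest median change of the 8 lists called in CM, 0.25 (camera adjusted p = 2.2e-04; adjusted p = 0.539 with an estimated correlation). By limma and edgeR 0 of 26 members passed over all genes, by DESeq2 0 of the 11 with an adjusted p, 5 had an unadjusted limma p under 0.05, and 3 were up adjusted over the list alone. The antiviral transcription factor genes Irf9 and Irf7 read 59.5 ± 10.9 and 99.0 ± 18.4 (0.73), and 18.3 ± 6.68 and 36.5 ± 3.31 (1.02). Endothelial markers had a median change of −0.06 (camera adjusted p = 0.0252; adjusted p = 0.618 with an estimated correlation), and 21 of 25 were lower. None passed by limma or edgeR over all genes, by DESeq2 (24 with an adjusted p) or adjusted over the list alone, and 1 had an unadjusted limma p under 0.05. The list lost its call without CM control replicate 2 (adjusted p = 0.301) or Wls fl/fl replicate 2 (adjusted p = 0.331).

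Wnt genes other than Wls were not called in CM by limma. By limma and edgeR 0 of the 5 tested ligands passed, DESeq2 gave an adjusted p for 2 and called 0, and 0 had an unadjusted limma p under 0.05. Wnt5a, a noncanonical ligand, read 73.6 ± 8.04 and 83.4 ± 8.68 (0.18, limma adjusted p = 0.732), and Wnt9a read 61.0 ± 13.6 and 69.9 ± 3.77 (0.21). Wnt5b and Wnt11, further noncanonical ligands, were near the lower limit of 10 and differed by 0.38 and 0.27, and Wnt7b by −0.47. The 35 Wnt receptors and noncanonical signalling genes had a median of −0.01 (camera adjusted p = 0.923), with 0 called by limma or edgeR, 0 of the 28 with an adjusted p by DESeq2, and 0 at an unadjusted limma p under 0.05. The 25 Yap and Taz target genes had a median of 0.01 (camera adjusted p = 0.551), with 0 called by limma or edgeR, 0 of the 21 with an adjusted p by DESeq2, 6 at an unadjusted limma p under 0.05 and 1 down adjusted over the list alone.

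In NonCM many genes differed. By camera with a preset correlation, lists of fibroblast and matrix genes were called up in Wls fl/fl hearts, and so were those of macrophages, neutrophils, interferon, complement, chemokines, epicardium, mitosis and immediate early genes. Lists of cardiomyocyte markers, sarcomere, calcium handling and energy metabolism were called down, as were endothelial markers, slightly. Mature cardiomyocyte markers took 8.43 ± 0.397% of reads in control and 7.07 ± 0.175% in Wls fl/fl libraries of this fraction. A lower share of cardiomyocyte RNA would lower cardiomyocyte genes and raise those of other cells. Its part in the changes below was not estimated. None of the 45 tested lists was called with an estimated correlation (lowest adjusted p = 0.0629).

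Of 13271 genes tested in NonCM by limma, 328 rose and 270 fell, and an unadjusted p under 0.05 was reached by 2565, where 664 would be reached by chance. All 598 called genes were also called by edgeR, which called 1485 (789 up, 696 down), and 496 were called in the deposited DESeq2 table, which holds 633 (335 up, 298 down). Most changes were small, with a median absolute log2 change of 0.39 and 30 genes at 1 or more. The count was 1634 without NonCM control replicate 1, 738 without control replicate 2, 120 without control replicate 3, 335 without Wls fl/fl replicate 1, 101 without Wls fl/fl replicate 2 and 77 without Wls fl/fl replicate 3. Without replicate 3 of both genotypes, limma called 0 genes (1242 at an unadjusted p under 0.05, lowest adjusted p = 0.139) and edgeR called 38 (32 up, 6 down). All 598 kept their direction by edgeR, which is no independent check, since the remaining libraries were among those that gave the calls. Of 108 genes chosen by the naming rule and called here, 30 kept their limma call whichever single library was left out, among them Fn1, Col1a1, Col3a1, Spp1, Saa3, Myom2 and Nppa. The other 78 lost it in at least 1 of the 6 such fits, with adjusted p up to 0.25.

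Among called genes with a mean of at least 50, the largest rise was of Esr1. It rose from 53.1 ± 30.9 to 723 ± 69.9 (3.88, SE 0.30, adjusted p = 8.7e-04). Saa3, an acute-phase protein (chromosome 7, 46711998 to 46715700), rose from 20.5 ± 3.88 to 144 ± 41.0 (2.74, SE 0.23, adjusted p = 8.7e-04). Spp1, or osteopontin, a matrix-bound cytokine of macrophages (chromosome 5, 104435118 to 104441050), rose from 15.0 ± 2.96 to 90.4 ± 33.7 (2.46, SE 0.29, adjusted p = 0.00317). Chil3, a chitinase-like protein of macrophages, rose by 3.09 (adjusted p = 0.0103), the integrin chain of white blood cells Itgb2 by 1.09 (adjusted p = 0.0187), and the microRNA locus Mir6236 by 1.45 (adjusted p = 0.0307). Col6a5, a collagen VI chain, rose from 42.6 ± 14.1 to 165 ± 14.3 (1.98, adjusted p = 0.00293), and Prg4, the lubricant proteoglycan of joints and scars, by 1.63 (SE 0.22, adjusted p = 0.00505).

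The largest fall was again of Thbs4, from 315 ± 11.8 to 60.1 ± 33.5 (−2.56, SE 0.38, adjusted p = 0.00929), with the call lost without NonCM control replicate 3 (adjusted p = 0.0519) or Wls fl/fl replicate 3 (adjusted p = 0.0504). Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), fell from 245 ± 14.8 to 147 ± 8.46 (−0.73, adjusted p = 0.00362). Myom2, a sarcomere M-band protein, fell from 15711 ± 399 to 10615 ± 580 (−0.57, adjusted p = 0.00138), and Lrrc10, a cardiomyocyte-specific sarcomere protein, from 918 ± 27.7 to 626 ± 33.3 (−0.55, adjusted p = 0.00216). Trim54, a muscle ubiquitin ligase, fell by 0.72 (adjusted p = 0.0241), Ramp1, a receptor partner for calcitonin gene-related peptide, by 0.73 (adjusted p = 0.0271), Fign by 0.60 (adjusted p = 0.0287), Sec31b by 0.61 (adjusted p = 0.0271), Asb18 by 0.57 (adjusted p = 0.0262) and RP23-281H4.12, a clone-based symbol without a position, by 0.57 (adjusted p = 0.0121).

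**Figure D2:**
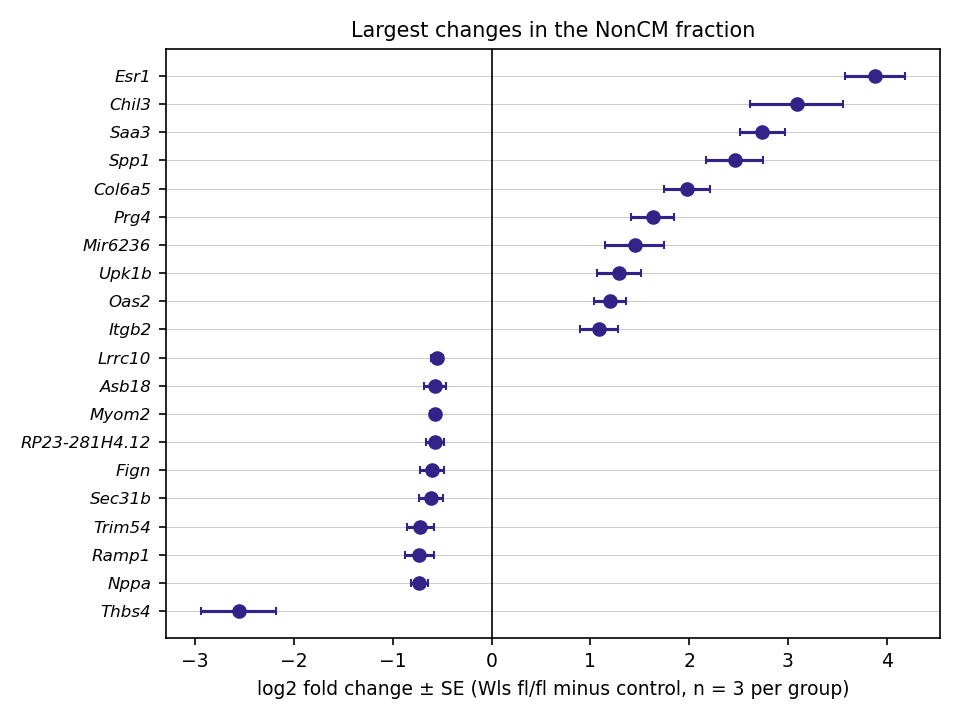
The 10 largest rises and the 10 largest falls in NonCM chosen by the naming rule, as log2 change of Wls fl/fl minus control on the horizontal axis, with bars for the standard error. Rises reach 3.88 for Esr1, and falls reach −2.56 for Thbs4.

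Of 45 lists tested in NonCM, camera called 28, of which 18 were up and 10 down. With an estimated correlation camera called 0, the lowest adjusted p being 0.0629, while fry called 27, of which 26 were among the 28. Without replicate 3 of both genotypes camera called 27 and fry 1, the genes of G2 and M phase (adjusted p = 0.0026).

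Fibroblast markers rose with a median of 0.46 (camera adjusted p = 2.3e-23; adjusted p = 0.0629 with an estimated correlation). Of 25 members 16 were up and 9 not called, and 22 were up adjusted over the list alone. The fibrillar collagen genes rose from already high levels, Col3a1 from 23591 ± 26.0 to 37089 ± 1187 (0.65, adjusted p = 6.4e-04) and Col1a1 from 10636 ± 96.1 to 16669 ± 1153 (0.65, adjusted p = 0.00112). Mfap5, a microfibril protein of fibroblasts, rose by 0.73 (adjusted p = 6.4e-04). Myofibroblast and fibrosis genes rose with a median of 0.43 (camera adjusted p = 1.3e-08; adjusted p = 0.0629 with an estimated correlation). Of 32 members 13 were up, Thbs4 was down and 18 were not called, and 16 were up and 3 down adjusted over the list alone. Fn1 (chromosome 1, 71585520 to 71653200) had the smallest p of all genes in NonCM and rose from 3482 ± 104 to 6419 ± 114 (0.88, SE 0.04, adjusted p = 9.8e-05). Col5a1, which seeds collagen fibrils, rose by 0.59 and Loxl1, which crosslinks elastin, by 0.54 (adjusted p = 0.00138 each). Basement membrane and other matrix genes rose with a median of 0.33 (camera adjusted p = 8.7e-19; adjusted p = 0.0629 with an estimated correlation), with 16 of 28 up, 12 not called and 21 up adjusted over the list alone. Col14a1 rose by 0.78, Col15a1 by 0.60 and the proteoglycan gene Bgn by 0.48.

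Matrix proteases and inhibitors rose with a median of 0.35 (camera adjusted p = 2.7e-08; adjusted p = 0.0962 with an estimated correlation). Of 21 members 7 were up and 14 not called, and 11 were up adjusted over the list alone. Adamts12 rose by 0.66 (adjusted p = 0.00322), and the gelatinase gene Mmp2 by 0.35 (adjusted p = 0.00388, its call lost in 1 fit that left out a library). Transforming growth factor beta signalling rose with a median of 0.18 (camera adjusted p = 2.1e-04; adjusted p = 0.0629 with an estimated correlation), with 3 of 27 up, 24 not called, and 6 up and 1 down adjusted over the list alone. The ligand gene Tgfb3 rose by 0.52 (adjusted p = 0.00659), and Ltbp3 and Ltbp4, which hold the latent ligand in the matrix, by 0.29 and 0.33 (adjusted p = 0.0305 and 0.0478). Late scar fibroblast genes were not called as a list (median 0.12, camera adjusted p = 0.374). They went both ways, with Prg4 up and 2 down among 11 tested, Thbs4 and Clu (−0.29, adjusted p = 0.0203), Clu being chosen after its values were seen.

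Epicardial markers rose with a median of 0.64 (camera adjusted p = 2.9e-06; adjusted p = 0.177 with an estimated correlation). All 12 were higher, 2 of them called and 8 up adjusted over the list alone. Aldh1a2, the retinoic acid enzyme of epicardium, rose by 0.83 and the mesothelial gene Upk1b by 1.29 (adjusted p = 0.0169 each), and Tbx18 read 47.3 ± 7.65 and 79.9 ± 15.4 (0.74, adjusted p = 0.0636). Innervation and axon guidance genes rose with a median of 0.19 (camera adjusted p = 0.00225; adjusted p = 0.0881 with an estimated correlation), with 4 of 17 up and 6 up adjusted over the list alone. The semaphorin genes Sema3c and Sema3d, secreted guidance cues, rose by 0.75 and 0.68 (adjusted p = 0.00149 and 0.00293), and Slit3 and the receptor gene Robo2 by 0.36 and 0.72 (adjusted p = 0.0201 and 0.0363). Schwann cell and neuronal markers were called up by camera with a median of 0.42 (camera adjusted p = 0.00346; adjusted p = 0.158 with an estimated correlation), with 0 of 8 members called by limma or edgeR or adjusted over the list alone, 0 of the 2 with an adjusted p by DESeq2, and 4 at an unadjusted limma p under 0.05.

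Macrophage and monocyte markers had a median of 0.32 (camera adjusted p = 4.3e-10; adjusted p = 0.0724 with an estimated correlation), with 3 of 26 up, 23 not called and 19 up adjusted over the list alone. The lysozyme gene Lyz2 rose from 1560 ± 97.0 to 2160 ± 20.5 (0.47, adjusted p = 0.0031), and Cd68 by 0.47 and Plac8 by 1.88 (adjusted p = 0.0229 and 0.027). Neutrophil markers had a median of 1.97 at low counts (camera adjusted p = 2.2e-05; adjusted p = 0.177 with an estimated correlation), with 1 of 10 up and 7 up adjusted over the list alone. Their libraries spread widely: Ltf, or lactoferrin, rose from 6.03 ± 1.75 to 60.3 ± 47.2 (2.73, adjusted p = 0.0472), and S100a9 read 28.3 ± 10.5 and 146 ± 91.2 (2.14, adjusted p = 0.053). Mast cell markers rose with a median of 0.61 (camera adjusted p = 0.00762; adjusted p = 0.16 with an estimated correlation), with 1 of 6 called, the protease gene Cpa3 (0.61, adjusted p = 0.0447), and 3 up adjusted over the list alone.

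Interferon-stimulated genes rose in NonCM with a median of 0.47 (camera adjusted p = 5.5e-12; adjusted p = 0.0629 with an estimated correlation). Of 35 members 8 were up, 27 not called, and 20 up adjusted over the list alone. The antiviral sensor gene Oas2 rose from 38.0 ± 4.73 to 88.8 ± 9.32 (1.20, adjusted p = 0.00493), Ifi27l2a by 0.84 and Ifi44 by 1.20 (adjusted p = 0.00691 and 0.0134). Chemokines and cytokines had a median of 0.75 (camera adjusted p = 1.3e-07; adjusted p = 0.0629 with an estimated correlation), with 4 of 21 up and 10 up adjusted over the list alone. The chemokine genes Ccl6, Ccl9 and Cxcl1 rose by 0.92, 0.71 and 1.06 (adjusted p = 0.00293, 0.0221 and 0.0276), beside Spp1. Complement and coagulation genes had a median of 0.38 (camera adjusted p = 1.1e-07; adjusted p = 0.0629 with an estimated correlation), with 5 of 18 up and 11 up adjusted over the list alone. C3, the central complement protein gene, rose from 1948 ± 289 to 3133 ± 438 (0.69, adjusted p = 0.0165), and Cd55, which restrains complement on cells, by 0.61 (adjusted p = 0.00633). Antigen presentation genes had a median of 0.13 (camera adjusted p = 0.0011; adjusted p = 0.0758 with an estimated correlation), with 3 of 19 up and 4 up adjusted over the list alone. The class I genes H2-K1, B2m and H2-D1 rose by 0.51, 0.45 and 0.40 (adjusted p = 0.00322, 0.00426 and 0.00732).

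Genes of G2 and M phase rose with a median of 0.44 (camera adjusted p = 2.6e-04; adjusted p = 0.0629 with an estimated correlation), with 2 of 27 up, over all genes and adjusted over the list alone. These were the proliferation marker gene Mki67 (0.58, SE 0.09, adjusted p = 0.0106) and the topoisomerase gene Top2a (0.56, SE 0.13, adjusted p = 0.0461). S phase genes had a median of 0.03 (camera adjusted p = 0.299), with 0 of 26 called by limma, 1 by edgeR, 0 of the 13 with an adjusted p by DESeq2, and 4 at an unadjusted limma p under 0.05. Unfolded protein response genes rose with a median of 0.16 (camera adjusted p = 1.3e-04; adjusted p = 0.161 with an estimated correlation), with 2 of 27 up, and 7 up and 1 down adjusted over the list alone. The endoplasmic reticulum folding genes Pdia4 and Calr rose by 0.45 and 0.22 (adjusted p = 0.00877 and 0.0322). Immediate early genes, which also respond to cell isolation, rose with a median of 0.28 (camera adjusted p = 2.0e-07; adjusted p = 0.177 with an estimated correlation), with 5 of 25 up and 12 up adjusted over the list alone. Fos rose from 1575 ± 59.6 to 2569 ± 400 (0.69, adjusted p = 0.00813), and Fosb by 0.81 (adjusted p = 0.0312).

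Cardiomyocyte genes fell together in NonCM. All 28 mature cardiomyocyte markers were lower, with a median of −0.27 (camera adjusted p = 3.4e-26; adjusted p = 0.0974 with an estimated correlation). Of these 21 were down, 7 were not called, and 27 were down adjusted over the list alone. Tcap, the titin cap gene, fell from 2257 ± 136 to 1599 ± 49.3 (−0.50, adjusted p = 0.00292), and troponin T, Tnnt2, by 0.40 (adjusted p = 0.00505). Sarcomere maturation isoforms had a median of −0.23 (camera adjusted p = 1.8e-11; adjusted p = 0.108 with an estimated correlation), with 9 of 20 down and 11 down adjusted over the list alone. Adult-type troponin I, Tnni3, fell by 0.30 and the ventricular myosin light chain gene Myl2 by 0.29 (adjusted p = 0.00929 and 0.0124). Fetal and stress cardiac genes had a median of −0.29 (camera adjusted p = 1.4e-07; adjusted p = 0.0694 with an estimated correlation), with 6 of 18 down and 10 down adjusted over the list alone, Nppa and the stretch sensor gene Csrp3 (−0.39, adjusted p = 0.00515) among them. Calcium handling and ion channel genes had a median of −0.26 (camera adjusted p = 2.1e-09; adjusted p = 0.0974 with an estimated correlation), with 9 of 27 down and 15 down adjusted over the list alone. Slc8a1, the sodium-calcium exchanger gene, fell by 0.28 and Ryr2, the calcium release channel gene, by 0.27 (adjusted p = 0.0101 and 0.0262).

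Nuclear-encoded oxidative phosphorylation had a median of −0.22 with all 48 members lower (camera adjusted p = 1.8e-28; adjusted p = 0.0974 with an estimated correlation), 22 down and 45 down adjusted over the list alone. The complex I genes Ndufa1 and Ndufs7 fell by 0.44 and 0.30 (adjusted p = 0.0144 and 0.0166). Fatty acid oxidation had a median of −0.22 (camera adjusted p = 1.1e-13; adjusted p = 0.0974 with an estimated correlation), with 11 of 28 down and 18 down adjusted over the list alone, Acadm and Acadl falling by 0.29 each (adjusted p = 0.0127 and 0.0219). Glycolysis had a median of −0.14 (camera adjusted p = 1.1e-04; adjusted p = 0.0629 with an estimated correlation), with 5 of 21 down, and 8 down and 2 up adjusted over the list alone, and the lactate dehydrogenase gene Ldhb fell by 0.28 (adjusted p = 0.0205). Mitochondrially encoded genes had a median of −0.12 (camera adjusted p = 0.00552; adjusted p = 0.431 with an estimated correlation), with 0 of 13 called by limma, 1 by edgeR, 0 of the 10 with an adjusted p by DESeq2, 2 at an unadjusted limma p under 0.05 and 0 adjusted over the list alone. That list lost its call without NonCM control replicate 2 (adjusted p = 0.149). Cytosolic ribosomal protein genes had a median of −0.05 (camera adjusted p = 0.0011; adjusted p = 0.0962 with an estimated correlation), with 0 of 47 called by limma or DESeq2, 1 by edgeR, 6 at an unadjusted limma p under 0.05 and 0 adjusted over the list alone. Endothelial markers had a median of −0.15 with 24 of 25 lower (camera adjusted p = 1.0e-05; adjusted p = 0.0962 with an estimated correlation), and 1 was down, over all genes and adjusted over the list alone, the sialomucin gene Emcn (−0.29, adjusted p = 0.0322). With the libraries' mean level of mature cardiomyocyte markers as a covariate, limma called 0 genes in NonCM and camera 14 lists. That level itself differed between the genotypes, by −0.29 with SDs of 0.04 and 0.06, so that the covariate stands in for genotype.

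**Figure D3:**
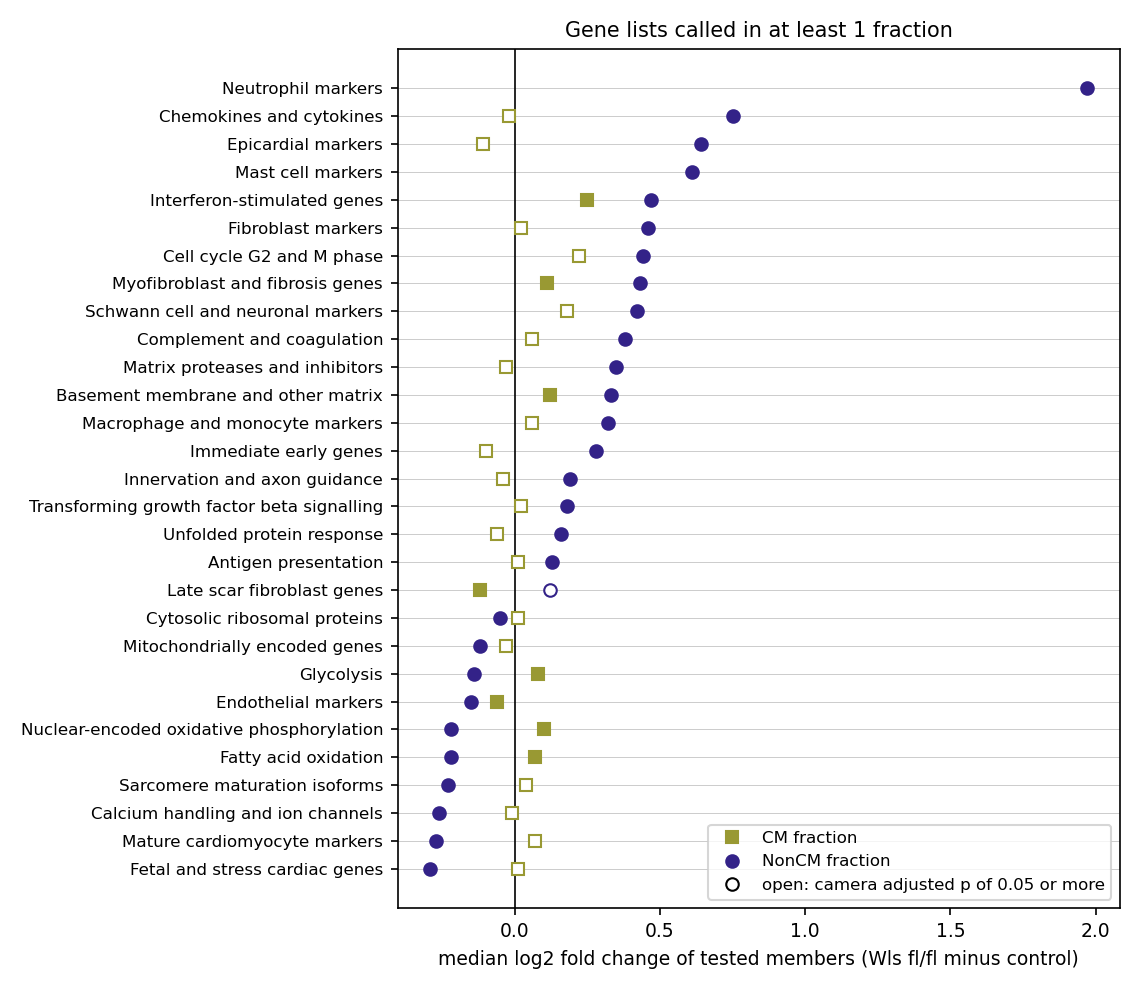
Median log2 change of the tested members of each list called in at least 1 fraction, with squares for CM and circles for NonCM, open where the camera adjusted p was 0.05 or more. Fibroblast markers lie at 0.02 in CM and 0.46 in NonCM, and oxidative phosphorylation genes at 0.10 and −0.22.

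No Wnt ligand was called in NonCM by limma. Of 8 tested, 1 had an unadjusted p under 0.05, edgeR called 1, DESeq2 gave an adjusted p for 2 and called 0, and the list had a median of 0.15 (camera adjusted p = 0.299). Wnt4 read 7.23 ± 6.89 and 25.8 ± 5.84 (2.37 by limma, adjusted p = 0.167; 1.34 by edgeR, adjusted p = 0.0177), with 0 reads in the shallow control replicate 1. Wnt5a differed by 0.21 (SE 0.10, adjusted p = 0.267), and Wnt11 read 35.2 ± 10.6 and 31.0 ± 7.41 (−0.16, adjusted p = 0.802). Receptors and noncanonical signalling genes were not called as a list (median 0.10, camera adjusted p = 0.113). Among its 35 members 2 rose, Ror1, a receptor for Wnt5a (188 ± 19.2 to 275 ± 10.2; 0.55, adjusted p = 0.0159), and Ptk7, a planar polarity receptor (0.48, adjusted p = 0.0272), and 5 were up and 2 down adjusted over the list alone. Sfrp1, a secreted Wnt antagonist, rose from 593 ± 69.1 to 868 ± 15.5 (0.55, adjusted p = 0.009), and was the 1 gene that limma called among 14 beta-catenin target and Wnt feedback genes, of which edgeR called 3 (median −0.06, camera adjusted p = 0.866). In the Wnt secretion list (median −0.01, camera adjusted p = 0.872), the glypican gene Gpc6 rose by 0.30 (adjusted p = 0.0286). Ror1 and Sfrp1 lost their calls in 3 of the 6 fits that left out a library, Ptk7 in 4 and Gpc6 in 5. Yap and Taz target genes (median 0.09, camera adjusted p = 0.376) went both ways, with 3 of 26 up, Myof at 0.62 (adjusted p = 0.00376) among them, and Ankrd1, a stretch-responsive cardiomyocyte gene, down by 0.53 (adjusted p = 0.0211).

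The fractions were compared to ask which effects of genotype they share. Log2 changes of 11820 genes tested in both correlated weakly across genes, which are not independent replicates (Pearson r 0.17, Spearman rho 0.08), and 51.9% had the same sign. Esr1, Ndrg4 and Prkg1 rose in both fractions, 3 genes where 0.195 would be shared by independent lists (Fisher's exact p = 7.3e-04, two-sided). Thbs4 fell in both (0.0685 by chance, Fisher's exact p = 0.067). The fractions are not independent, since NonCM also held cardiomyocyte RNA (mature markers at 8.43% of reads in control, against 12.4% in CM control). A change in cardiomyocytes alone would therefore be read in both fractions. These tests cannot decide whether cells other than cardiomyocytes share the changes. A joint edgeR fit of all 12 libraries gave 116 genes whose effect of genotype differed between fractions, 42 of them higher in NonCM and 74 lower, with 1720 at an unadjusted p under 0.05. Matrix genes gained more in NonCM, with differences of NonCM minus CM of 0.53 for Fn1 and 0.50 for Col3a1 (edgeR adjusted p = 0.0188 and 0.0359). Genes of respiration parted the other way, with −0.43 for Cox5b (adjusted p = 0.0306). Of 42 lists, fry called 16 as differing, among them oxidative phosphorylation (median difference −0.30, adjusted p = 0.00287), mature cardiomyocyte markers (−0.31, adjusted p = 0.00287) and fibroblast markers (0.46, adjusted p = 0.00329). Interferon-stimulated genes, higher in both fractions, were not shown to differ (median difference 0.21, adjusted p = 0.118). Mature cardiomyocyte markers took a like share of reads in both genotypes in CM (12.4% and 12.5%). In NonCM their share was lower in Wls fl/fl libraries (8.43% in control, 7.07% in Wls fl/fl). Such a shift in 1 fraction alone would part cardiomyocyte genes from those of other cells in these directions. The differences therefore need not be changes of expression within cells. The comparisons between fractions treat the 12 libraries as separate hearts. The labels do not say whether a CM and a NonCM library share a heart, and changes measured in the same hearts would share their variation.

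Among named genes with coordinates, 20 of 45 in CM and 70 of 146 in NonCM overlap another annotated gene. The sources used here do not say whether counting used the strand of the reads, so reads of overlapping and antisense genes cannot be separated.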

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

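The joint fit of both fractions, every test of Esr1, the tests of a lower cardiomyocyte share and of the shallow library, and those of replicate 3 as a mixture or as a separate heart were chosen after the result was seen. The effect of genotype was compared between fractions by the interaction term of a joint edgeR fit, for 155 named genes and 27 lists, and 28 genes and 15 lists differed. This fit had no replicate block and counted replicate 3 as independent. With a block of libraries whose numbers differ by 6, further genes were called, such as Thbs4 (edgeR adjusted p = 5.3e-04, from 0.0612) and Col1a1 (0.00698, from 0.133). So were the macrophage (fry adjusted p = 0.0354, from 0.285) and epicardial lists (0.0204, from 0.119). Values below are log2 differences of the effect without the block, NonCM minus CM. They also hold any shift in the share of cardiomyocyte RNA. The share of its markers was lower in Wls fl/fl than in control libraries in NonCM (7.07% against 8.43%) and alike in CM (12.5% against 12.4%). No group had enough libraries for a test of single outlying samples.

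Matrix and fibroblast genes gained more in NonCM, with 0.53 for Fn1, 0.50 for Col3a1, 0.51 for Col5a1, 0.38 for Col6a2, 0.46 for Fstl1, 0.68 for Mfap5, 0.48 for Mmp2, 0.48 for Timp2 and 0.78 for Tgfb3. The antigen presentation genes H2-D1 and H2-K1 differed by 0.38 and 0.43, and the folding gene Pdia4 by 0.60. Sarcomere and calcium genes were lower in NonCM by comparison, with −0.34 for Myh7, −0.35 for Myl2, −0.33 for Tnni3, −0.44 for Lrrc10 and −0.42 for Ryr2. So were genes of respiration and fatty acid oxidation, with −0.43 for Cox5b, −0.41 for Cox7b, −0.44 for Ndufa1, −0.36 for Ndufs7, −0.35 for Uqcrfs1, −0.31 for Uqcrh, −0.36 for Acadl, −0.33 for Acadm and −0.37 for Eci1. Esr1 differed by −1.91 and Wls by 1.17.

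Lists that differed by fry, as the median of the difference over members, were fibroblast markers (0.46), matrix proteases and inhibitors (0.38), chemokines and cytokines (0.39, not called with the replicate block, adjusted p = 0.129), basement membrane and other matrix (0.30), antigen presentation (0.25), myofibroblast and fibrosis genes (0.24), the unfolded protein response (0.23) and transforming growth factor beta signalling (0.12). Mature cardiomyocyte markers (−0.31), nuclear-encoded oxidative phosphorylation (−0.30), sarcomere maturation isoforms (−0.29), fetal and stress cardiac genes (−0.29), fatty acid oxidation (−0.28), calcium handling and ion channels (−0.24) and glycolysis (−0.24) differed the other way.

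Fibroblast genes up and cardiomyocyte genes down in NonCM. The mean log2 level of fibroblast minus endothelial markers differed by 0.67 between genotypes (pooled SD 0.02, n = 3 per group). A lower share of cardiomyocyte RNA could give part of this, and how large a part was not estimated. From CM to NonCM control, fibroblast markers went from 0.169% to 1.47% of reads, and endothelial markers only from 0.319% to 0.485%. Such a lower share would still raise endothelial markers. Their mean level was lower by 0.15 (SDs 0.08 in control and 0.04 in Wls fl/fl), which argues against it as the whole account. Whether a lower share accounts for the fall of cardiomyocyte genes is not decided by this test. In CM the mature cardiomyocyte markers did not fall as a set (median 0.07, 8 of 28 lower), and all 48 oxidative phosphorylation genes were higher. This argues against lower expression of these lists in the cardiomyocytes of both fractions alike. Lower expression only in cardiomyocytes of NonCM cannot be told apart from a lower share of their RNA. More fibroblasts with an unchanged profile would raise by a common amount only those markers that are read from fibroblasts alone. The fibroblast markers' changes spread by 6.78 times their squared errors, from −0.01 (Vtn) to 1.38 (Cxcl14). The changes were thus unequal, but this cannot exclude that account. Vtn is also in the list of mural cell markers, other members may be read from other cells, and the errors count replicate 3 as independent. The shallow NonCM control replicate 1 is argued against, since the markers' median change without it was 0.49. More fibroblasts, a changed fibroblast profile or both may remain as an effect of the genotype, and the libraries hold no cell counts with which to tell these apart.

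Esr1 high in the Wls fl/fl libraries of both fractions. Higher Esr1 of interstitial cells is argued against, since its excess as a share of all reads was 2.28 times as large in CM as in NonCM. Reads from the estrogen receptor part of the MCM allele may account for it, since the excess per 1000 Myh6 reads overlapped between the fractions (ratio of CM to NonCM 1.23, library ranges 4.52 to 6.44 and 4.26 to 5.13), as for a transcript made in cardiomyocytes, although CM was higher in 3 of 3 pairs of libraries whose numbers differ by 6. That reading needs the MCM allele to be read differently in the genotypes, since cardiomyocyte Esr1 was 68.3 times as high in Wls fl/fl as in control libraries although the labels give MCM/+ to both. If the controls lacked a working MCM allele, each difference between genotypes would hold an effect of Cre beside that of Wls, and no group here separates these. A rise of the mouse's own Esr1 in cardiomyocytes with the genotype stays open and untested, as the values do not say which exons were read.

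Replicate 3 between replicates 1 and 2 in each of the 4 groups. Replicate 3 may hold RNA or cells of the samples of replicates 1 and 2, as a weighted mean of them left 1.04 times the counting variance at most, without the 1% largest residuals. That variance adds those of replicate 3 and of the weighted mean. In NonCM control the noise of the shallow replicate 1 therefore makes it a weak test. Weights on replicate 1 were 0.56, 0.79, 0.49 and 0.31 in CM control, CM Wls fl/fl, NonCM control and NonCM Wls fl/fl. Assembly from the sequencing reads of those replicates is argued against, since NonCM control would need 4499382 reads from replicate 1, which holds 1160146. A separate heart cannot be told apart from such a mixture. For a replicate number named beforehand, being the library between in all 4 groups has a chance of 0.0123 if the groups are independent. The chance is 0.111 if the fractions share hearts. Replicate 3 was picked after the values were seen, so the chance that any 1 replicate number does so is larger. Hearts that vary along 1 axis would also lie on a line. No biological explanation was tested.

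The 6 libraries of a fraction make 10 splits into 3 and 3, too few for a share under 0.05. In NonCM the real split called 598 genes and the highest other 0, and in CM 11 and 3, so that in both fractions 1 split, the real one, called as many.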

How the results depend on the processing

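The fits without replicate 3 of both genotypes, limma-voom and the replicate block were chosen after the results were seen, and all other alternatives before. No paired analysis of the genotypes was possible because the labels share no replicate number between them. In the joint fit, a replicate block of CM and NonCM libraries whose numbers differ by 6 gave 581 genes differing between fractions in place of 116, all 116 among them. It gave 18 lists in place of 16, with 15 in both, and chemokines and cytokines lost their call (adjusted p = 0.129). Neither joint fit was repeated without replicate 3. Of 8 lists called in CM, 129 of 167 alternative values kept direction and call and 38 only the direction; of 28 in NonCM, 535 of 585 kept both, 43 only the direction and 7 turned. Of 845 values for 45 named CM genes 803 kept direction and side of the threshold, 33 lost and 8 gained a call and 1 turned; of 2736 for 146 NonCM genes 2031 did, 595 lost, 70 gained and 40 turned. TMM and upper-quartile scaling moved the median of all genes by at most 0.012 and turned no called list. Depth limits low genes most in NonCM control replicate 1. The cause was not tested except where named.

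The 11 CM genes became 41 with no filter, 25 by DESeq2, 17 by edgeR, 17 by limma-voom, 25 with the covariate of the other fraction's markers, 23 with the sex-linked covariate, 21 at an adjusted p under 0.1, 4 with an absolute log2 change of at least 1, 5 to 18 with a library left out, and 2 without replicate 3 by limma and 2 by edgeR, where fewer libraries were fitted. CM lists numbered 5 at a mean of 50, 0 with an estimated correlation, 1 by fry and 7 to 9 with a library left out. CM Wls was −1.60 by limma and −1.60 by edgeR without replicate 3 (adjusted p = 0.0898 and 0.0859), and −1.57 to −1.22 with a library left out. Fmod in CM was 0.02 without control replicate 1 and −0.74 to 0.02 over all libraries left out.

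The 598 NonCM genes became 1485 by edgeR, 1477 by limma-voom, 323 with the sex-linked covariate, 1120 at an adjusted p under 0.1, 30 with an absolute log2 change of at least 1, 77 to 1634 with a library left out, 0 (limma) and 38 (edgeR) without replicate 3, and 0 with the cardiomyocyte marker covariate, which differed between genotypes by −0.29 with SDs of 0.04 and 0.06 and so stands in for genotype. NonCM lists numbered 14 with that covariate, 0 with an estimated correlation, and 28 to 29 with a library left out. NonCM Wls was −0.25 by edgeR, −0.25 by limma-voom and −0.33 to −0.24 with a library left out. The correlation between fractions (0.17) was 0.29 at a mean of 50, 0.20 from the deposited fold changes, 0.13 without replicate 3, and 0.14 to 0.21 with a library left out.

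With the cardiomyocyte marker covariate, changes of opposite sign in NonCM were 0.08 for Acadl, 0.42 for Ankrd1, −0.52 for Btg2, −0.78 for Bub1b, −2.00 for Chil3, −0.47 for Cxcl1, −0.10 for Dusp1, 0.10 for Etfa, −0.26 for Fos, −0.43 for Fosb, −0.12 for Igf1, 0.02 for Ldhb, −0.12 for Ltbp4, −2.27 for Ltf, 0.01 for Ndufa1, −4.35 for Ngp, 0.02 for Pdk1, 0.07 for Pln, 0.12 for Rps2, −3.77 for S100a8, −2.97 for S100a9, 0.25 for Wls, 0.15 for Wnt11, −0.37 for Wnt2b, −1.41 for Wnt4, −0.86 for Wnt9a, −3.27 for Wnt9b, 0.41 for mt-Nd3 and 1.45 for mt-Nd4l. List tests turned for calcium handling (median 0.07), fatty acid oxidation (0.02), oxidative phosphorylation (0.05), matrix proteases (0.21), sarcomere isoforms (0.00), neutrophil markers (−2.67, adjusted p = 2.0e-04) and immediate early genes (−0.39, adjusted p = 4.6e-06). Wnt ligands that were not called also changed sign in NonCM. Wnt11 was −0.41 to 0.03 with a library left out (0.03 without control replicate 1, 0.00 without Wls fl/fl replicate 1) and 0.01 with the sex-linked covariate. Wnt2 was −0.39 (without control replicate 3) to 0.50 with a library left out, and −0.37 (limma) and −0.18 (edgeR) without replicate 3. Wnt2b was −0.05 (without Wls fl/fl replicate 2) to 0.07, −0.00 without control replicate 1, −0.02 with the sex-linked covariate and −0.01 by limma-voom. Wnt9a was −0.00 by edgeR and −0.06 (without control replicate 1) to 0.44 with a library left out.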

Other observations

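The test of chromosomes was chosen after the result was seen, and the test of library numbers before it. Lists that camera did not call in NonCM also held called genes. Among secreted cardiomyocyte factors (median 0.04, camera adjusted p = 0.872), Fstl1, a secreted follistatin-like glycoprotein, rose from 3455 ± 173 to 5261 ± 67.1 (n = 3; log2 change 0.61, limma adjusted p = 8.7e-04) while Nppa fell. Angiogenic factors and receptors had a median of −0.01 (camera adjusted p = 0.95), with the growth factor genes Igf1 and Fgf2 up by 0.48 and 0.42 (adjusted p = 0.0108 and 0.0354) and 25 of 27 not called. Prox1, which sets lymphatic identity and is also expressed in cardiomyocytes, fell by 0.42 (adjusted p = 0.0129), in a list of 8 with a median of −0.10. Among mural cell markers (median 0.03, camera adjusted p = 0.327), Des and Abcc9, both also expressed in cardiomyocytes, fell by 0.31 and 0.22 (adjusted p = 0.0101 and 0.0374). Sod3, the secreted superoxide dismutase gene, rose by 0.44 (adjusted p = 0.0117) in a list of oxidative stress genes with a median of −0.05, and the linker histone gene Hist1h1a rose by 1.14 (adjusted p = 0.0419).

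Genes with few reads, chosen after their values were seen, also rose in NonCM by limma. The macrophage genes Arg1, Marco and Mmp12 went from 4.51 ± 5.02 to 36.1 ± 6.72, from 11.6 ± 0.559 to 45.5 ± 3.24 and from 11.1 ± 0.291 to 39.1 ± 9.67 (n = 3; adjusted p = 0.0403, 0.00292 and 0.0108). Scgb1a1, a secretory gene of airway epithelium, went from 5.44 ± 4.91 to 33.3 ± 10.4 (adjusted p = 0.0262), while lung epithelial markers as a list took 0.0135 ± 0.0011% and 0.0129 ± 2.6e-04% of NonCM reads. In CM, the sarcomere genes Myom2 and Tcap, chosen after their values were seen, differed by −0.26 and −0.25 (limma adjusted p = 0.0502 and 0.0638; DESeq2 adjusted p = 4.1e-04 and 0.0112), while mature cardiomyocyte markers had a median of 0.07 (camera adjusted p = 0.0748). 4833420G17Rik (chromosome 13, 119462768 to 119486120), chosen likewise, read 56.6 ± 10.8 and 26.1 ± 3.61 in CM (adjusted p = 0.0682) and 98.3 ± 14.5 and 58.0 ± 8.27 in NonCM (adjusted p = 0.034). The atrial light chain genes Myl7 and Myl4, chosen likewise, were low in Wls fl/fl replicate 1 of both fractions, at 12.9 and 14.1 in CM and 15.9 and 20.3 in NonCM, against 251 and 179 in CM and 222 and 166 in NonCM of Wls fl/fl replicate 2.

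Chromosome 19 held 12 of the 100 CM genes of smallest p where 3.46 would fall by its share (Fisher's exact test, adjusted over chromosomes, p = 0.00372), Prkg1 among them, while in NonCM no chromosome passed (lowest adjusted p = 0.0723, chromosome 1). DNA that differs between the genotypes around a locus on chromosome 19 may contribute, and the sources used here do not say where the MCM allele lies.

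The library numbers of corresponding CM and NonCM libraries differ by 6, and the difference between replicates 1 and 2 correlated across genes between the fractions (r 0.32 in control and 0.15 in Wls fl/fl hearts, over 8427 genes). Libraries whose numbers differ by 6 may come from the same heart. The test does not decide this, since it used 1 difference per genotype and genes that are not independent replicates. Swapping the pairs would only turn the sign of r.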
